A study of Mus musculus with 8 samples.

How the data were processed

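Gene expression was measured by mRNA sequencing of 8 libraries of sorted mouse tumour neutrophils, 4 ICAM1high and 4 ICAM1low, each made from 100 ng of total RNA. The authors deposited 1 table of read counts per gene for 54532 genes, with gene names, positions, biotypes and the gene length in bases; the values were whole numbers with no normalization, and the deposited gene length is an other quantity that was used only to compare short with long genes. The submitters' processing notes name HISAT2, a spliced aligner, and the mouse genome mm10; the version, the counting tool, the annotation release, the strand setting and any filters are not given in the sources used here. Of the gene IDs, 54409 (99.8%) were found in the GENCODE M21 annotation, and 98.3% of those had the same position there. Reads of related genes, such as stefins or H2 genes, or of genes that overlap on opposite strands, may have been counted for either gene. Of 108 named genes, 9 overlap another gene that holds at least 10% of their counts. Totals of 10328575 to 22751975 counts per library set the precision of low values. Replicates differed by far more than counting error, with a chi-square per degree of freedom of 12.8 to 228 between libraries of a group. The replicates are biological per the labels, but nothing says that each came from its own mouse, so p-values measure the spread between samples. Replicates of the fractions share library numbers, which may mean that they came from the same tumours. The main comparison is unpaired because the labels state no pairing, and a replicate block was an alternative. Correlations between same-numbered libraries after removal of the group means were -0.57, 0.21, 0.18 and -0.30. These do not settle the pairing, since the negative values are of the pairs with ICAM1high replicate 1 and ICAM1low replicate 4, which stood apart from their groups.

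Analyses were run in R 4.3.3. Genes were filtered with filterByExpr by group at its defaults, which left 14051, scaled by TMM, and tested with the quasi-likelihood F test of edgeR 4.0.16 (default prior, no robust option). P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are ICAM1high over ICAM1low on the log2 scale, and standard errors were taken as the size of the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM used a prior count of 2. The 33 gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. Lists with at least 5 measured members, 30 in all, were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists; camera compares a list with all other genes. With an estimated correlation 0 of the 17 calls passed. The test fry, which asks whether a list moves one way on balance without comparing it with other genes, called 21 lists. Shares of counts per library and mean log2 CPM of cell type lists, 16 measures, were compared by exact two-sided permutation tests, whose smallest possible p is 0.0286 with 4 against 4.

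Named genes were Icam1, the 10 genes with the largest positive and the 10 with the most negative log2 fold change, and up to 3 members of each list with the smallest p. The largest changes were taken among genes with an adjusted p under 0.05, an average log2 CPM of at least 3 and the same sign in all 4 same-numbered differences, without predicted genes, pseudogenes and receptor segments; list members needed an average log2 CPM of at least 1. Some members outside this rule, mostly of counts of 5 or fewer, were named after their values were seen. Icam1 is in no list.

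On simulated data with the spread of these libraries, in which 200 genes were changed, edgeR recovered 80.3% of the 66 genes changed 4-fold, 20.9% of the 67 changed 2-fold and 1.49% of the 67 changed 1.5-fold, with 1 false call among 69. For the interaction with the library-number run it recovered 25.8% of genes changed 4-fold. With so few changed genes the adjusted threshold is stricter than in the comparison of the fractions, where 42.1% of genes passed. These rates therefore do not measure power in that comparison. All 5 raised lists were called, and 0 of 13 lists without raised genes. Genes were simulated independently, so this does not test lists whose genes vary together. In the data the estimated correlation ran from -0.003 for adhesion molecules to 0.77 for oxidative phosphorylation, and was 0.44 for core neutrophil genes.

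Alternatives fixed beforehand were DESeq2 1.42.0 and limma-voom as tools, RLE and upper-quartile scaling, no filter and a filter of 50 counts in 4 libraries, robust dispersion, a replicate block, the library-number run as a covariate, each run alone, each library left out in turn, and, for lists, an estimated correlation, fry and the block with an estimated correlation. Added after the data were seen were scaling by library totals alone, the same with fry, leaving out ICAM1high replicate 1 and ICAM1low replicate 4 together, and thinning every library to the smallest total. No library was left out of the main comparison. Raw reads, transcript isoforms and strand-specific counts were not analysed here.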

Results

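RNA sequencing was performed on neutrophils recovered from mouse mammary tumours that had been grown from 2208L cells, a mouse mammary tumour line, in the mammary fat pad of Balb/c mice. Tumours were taken at a diameter of 1 cm and dissociated, and flow cytometry separated the infiltrating neutrophils into an ICAM1high and an ICAM1low fraction. ICAM1, also called CD54, is an adhesion molecule that binds beta2 integrins. Each fraction was represented by 4 biological replicates, which gave 8 libraries. Total counts in ICAM1high replicates 1 to 4 were 20625309, 17556363, 16116880 and 10328575. The ICAM1low replicates 1 to 4 held 16768777, 18924939, 22374245 and 22751975 counts. The totals averaged 16.2 ± 4.32 M counts in ICAM1high and 20.2 ± 2.87 M counts in ICAM1low (SD, n = 4, exact permutation p = 0.171). At least 1 count was found for 20282.8 ± 952.9 genes per ICAM1high library and 17692.5 ± 1325.3 genes per ICAM1low library (SD, n = 4, exact permutation p = 0.0571). PC1 held 58.4% of the variance and separated the fractions, whereas PC2 held 22%. ICAM1high replicate 1 and ICAM1low replicate 4 lay apart from the rest of their groups on PC2, and both had relatively more counts in short genes.

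**Figure D1:**
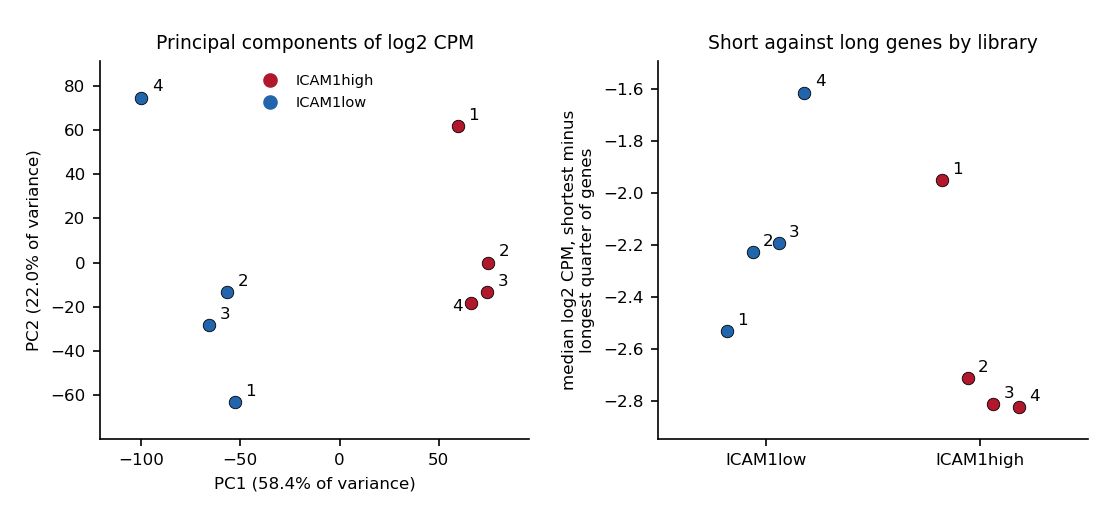
Left, each point is 1 library on PC1 and PC2 of log2 CPM, with its replicate number, in red for ICAM1high and blue for ICAM1low. Right, the median log2 CPM of the shortest genes minus that of the longest genes is plotted per library, with ICAM1high replicate 1 at -1.95 and ICAM1low replicate 4 at -1.61 as the highest point of each group.

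The comparison of ICAM1high with ICAM1low tumour neutrophils asked how the transcriptomes of the fractions differ, in a study concerned with neutrophil adhesion, reverse migration and metastasis. ICAM1high cells held far more transcript of genes typical of macrophages, such as Axl, a receptor for apoptotic cells, at 239 ± 31.6 against 7.98 ± 4.49 CPM, and Mmp12, the macrophage elastase, at 54.2 ± 2.37 against 1.49 ± 0.532 CPM (SD, n = 4). They held far less of classical neutrophil genes, including S100a8, a subunit of calprotectin, at 1029.9 ± 393 against 8996 ± 6588 CPM, and Retnlg, a resistin-like gene of neutrophils, at 9.54 ± 5.12 against 375 ± 411 CPM. In ICAM1low, replicate 4 held S100a8 at 18812 and Retnlg at 984 CPM, against 4669 to 6443 and 117 to 262 in the other 3. Of 14051 genes tested, 3172 were higher and 2748 were lower in ICAM1high, and 2115 and 1704 of these changed at least 2-fold. The sorted marker itself rose: Icam1 (ENSMUSG00000037405, mm10 chromosome 9, 21015985 to 21028817) measured 1459 ± 202 against 848 ± 214 CPM, a log2 fold change of 0.78 (SE 0.20, adjusted p = 0.0105), higher in 4 of 4 same-numbered pairs. In replicates 1 and 2 alone the Icam1 difference was 0.52 with an adjusted p of 0.258. Among genes with an average log2 CPM of at least 3 and a shared sign in all 4 pairs, the largest increases besides Mmp12 and Axl were in Col14a1, a fibril-associated collagen (ENSMUSG00000022371, chromosome 15, 55307750 to 55520803), at 5.83 (SE 0.49, adjusted p = 1.7e-05), Lilra5, a leukocyte immunoglobulin-like receptor, at 5.65 (SE 0.35, adjusted p = 3.29e-06), and Ms4a14 at 5.50 (SE 0.70, adjusted p = 0.000216). Adgrg5, Kcnj10, Frmd4b, Zmynd15 and Plxdc2 rose by 5.22, 5.18, 4.97, 4.93 and 4.91 on the log2 scale. Zmynd15 overlaps Cxcl16 on the other strand, and the strand setting of the counting is not given in the sources used here. By the same rule, the largest decreases were in Retnlg (ENSMUSG00000022651, chromosome 16, 48872621 to 48874496), at -5.31 (SE 0.78, adjusted p = 0.000485), and Ngp, a granule protein of maturing neutrophils, at -4.90 (SE 0.90, adjusted p = 0.00176). Fosl1, an AP-1 subunit, Ifitm6, the stefins Stfa3 and Stfa2, and the chemokine-like Prok2 changed by -4.30, -3.97, -3.96, -3.74 and -3.67. Rdh12, Ly6g, the antigen recognised by neutrophil-specific antibodies, and S100a8 changed by -3.24, -3.22 and -3.13. All but Rdh12 leaned on ICAM1low replicate 4: without it Retnlg was at -4.19, Ngp at -4.09, Fosl1 at -3.68, Ifitm6 at -3.07, Stfa3 at -2.55, Stfa2 at -2.77, Prok2 at -2.67, and Ly6g and S100a8 at -2.47 each, and all still passed. Slc2a3, a glucose transporter, then fell further than Ifitm6, the stefins, Prok2, Ly6g and S100a8, at -3.09. Without ICAM1high replicate 4, Ngp, Stfa3 and Prok2 were at -5.67, -4.56 and -4.41. Ms4a14 was at 6.86 without ICAM1low replicate 1 and Kcnj10 at 5.79 without ICAM1low replicate 3. Reads of closely related stefin genes can be hard to assign to a single gene.

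The balance of directions depended on the scaling of the libraries. The 10 most counted genes took 12.7 ± 2.26% of counts in ICAM1low and 7.04 ± 1.19% in ICAM1high (SD, n = 4, exact permutation p = 0.0286, adjusted 0.0457 over 16 measures). With TMM scaling 53.6% of calls were higher in ICAM1high, and with library totals alone 89.0% were, as 6818 genes rose and 839 fell. The median log2 fold change of all tested genes was 0.08 with TMM and 0.76 with library totals, a shift of 0.68, and fold changes are given relative to the TMM scale.

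**Figure D2:**
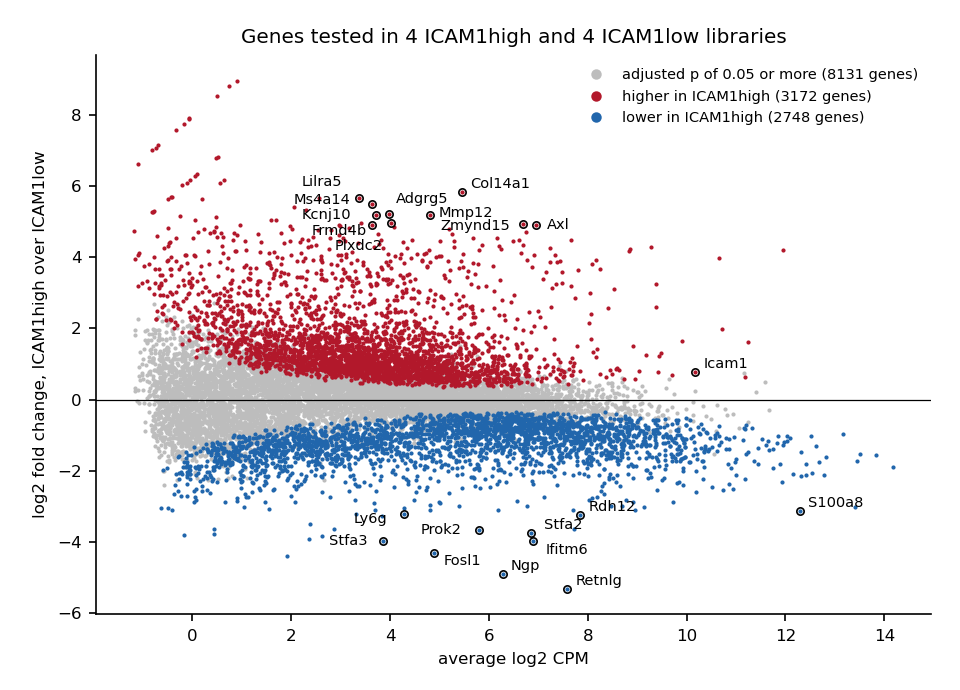
Each point is a tested gene, with its average log2 CPM on the x axis and its log2 fold change of ICAM1high over ICAM1low on the y axis, coloured by direction among genes with an adjusted p under 0.05. The 3172 higher and 2748 lower genes are those under TMM scaling, where 53.6% of calls were higher, whereas 89.0% of calls were higher under library totals.

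Macrophage genes and genes of MHC class II presentation rose together in ICAM1high. Adgre1, which encodes F4/80, reached 329.7 ± 35.9 against 27.2 ± 3.51 CPM, and Selenop, a selenium transport protein, reached 507 ± 75.3 against 35.9 ± 5.29 CPM (SD, n = 4). Their log2 fold changes were 3.60 (SE 0.17, adjusted p = 1.04e-06) and 3.82 (SE 0.18, adjusted p = 1.04e-06). Of 25 macrophage and monocyte markers, 23 rose, 0 fell and 2 did not pass (23 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 3.82. The 2 that did not pass were Ly6c2, a monocyte antigen, at -1.11 and Ctsk, a cathepsin, at -0.13, and Csf1r, the receptor for CSF1, rose by only 0.78; these 3 were picked after their values were seen. This list was called higher by camera (adjusted p = 1.43e-13), and had an adjusted p = 0.0833 with an estimated correlation. Of 17 genes of MHC class II presentation and co-stimulation, 14 rose and 0 fell (15 and 0 when adjusted over the list alone), with a median of 3.20. Cd83, a maturation marker of antigen-presenting cells, was at 197 ± 18.4 against 9.67 ± 1.51 CPM with a log2 fold change of 4.34 (SE 0.18, adjusted p = 1.04e-06). The co-stimulatory ligand Cd86 rose by 1.90 and the protease Ctss, which trims the invariant chain, by 2.60. The members that did not pass were H2-Ob at 1.79, Cd80 at -0.56 and Icosl at 0.11, also picked after their values were seen. Camera gave this list an adjusted p = 1.63e-07, and an adjusted p = 0.189 with an estimated correlation. Class I presentation was mixed: 7 of 22 genes rose and 2 fell (7 and 4 when adjusted over the list alone), and camera gave an adjusted p of 0.856. H2-M3, a non-classical class I gene, rose by 3.36, the peptide-trimming Erap1 by 1.76 and the chaperone Pdia3 by 1.06. The 2 that fell were H2-Q4 at -0.63, which turned to 0.05 under library totals, and H2-T23 at -1.04, both picked after their values were seen. H2 genes share sequence, and Erap1 overlaps Cast on the other strand.

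Neutrophil identity genes were lower in ICAM1high in every member of the core list. Hdc, the histamine-forming enzyme, was at 1731 ± 314 against 7392 ± 1237 CPM, and Trem1, an amplifier of myeloid inflammation, was at 559.9 ± 79.2 against 2061 ± 379.9 CPM (SD, n = 4), with log2 fold changes of -2.09 (SE 0.19, adjusted p = 2.97e-05) and -1.88 (SE 0.18, adjusted p = 3.87e-05). Acod1, which makes itaconate, fell by 2.05 on the log2 scale. Of 20 core neutrophil genes, 20 fell and 0 rose, also when adjusted over the list alone, with a median of -2.10, and 19 fell under library totals, where Mmp9, a gelatinase, turned from -0.56 to 0.12. Camera called the list lower (adjusted p = 3.55e-11), with an adjusted p = 0.198 with an estimated correlation. Of 25 genes of circulating mature neutrophils, 24 fell and 1 rose, also when adjusted over the list alone, with a median of -2.11 and an adjusted p of 3.94e-11 (adjusted p = 0.206 with an estimated correlation); 10 of the 25 are also core genes. Padi4, which citrullinates histones, changed by -2.58, and Mxd1, a MYC antagonist, by -1.81. The member that rose, picked after its value was seen, was Lyz2, lysozyme of neutrophils and macrophages, at 1.98. Among 20 secondary and tertiary granule genes 16 fell and 1 rose, also when adjusted over the list alone, with a median of -1.76 and an adjusted p of 9.41e-07 (adjusted p = 0.258 with an estimated correlation). Adam8, a sheddase stored in granules, changed by -2.34 and Anxa1, a pro-resolving protein, by -1.61. Cybb, the catalytic subunit of the phagocyte oxidase, rose by 2.40, and Chil3 at -1.21, Serpinb1a at -0.91 and Arhgdib at -0.58, picked after their values were seen, did not pass. Only 3 primary granule genes were measured: Ctsc, a protease that activates granule serine proteases, rose by 2.58, Prtn3, proteinase 3, changed by -1.46 and did not pass under library totals (-0.77, adjusted p = 0.0598), and Cd63 was at 0.36 (SE 0.28, adjusted p = 0.325) but passed under library totals (1.05, adjusted p = 0.00435). Prtn3 overlaps Plppr3 on the other strand. Of 35 genes of tumour neutrophils of the SiglecF-high or TRAIL decoy receptor type, 17 fell and 7 rose (18 and 9 when adjusted over the list alone), with a median of -0.86 and an adjusted p of 0.00671 (adjusted p = 0.464 with an estimated correlation). Within it Cxcl3, a neutrophil chemoattractant, and Plaur, the urokinase receptor, changed by -2.99 and -2.31; under library totals 12 members rose and 10 fell. In the same libraries, macrophage and monocyte markers had a mean log2 CPM of 6.71 ± 0.160 in ICAM1high and 3.31 ± 0.176 in ICAM1low, and core neutrophil genes 9.11 ± 0.320 and 11.3 ± 0.443 (SD, n = 4, exact permutation p = 0.0286 for each, the smallest the design allows).

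**Figure D3:**
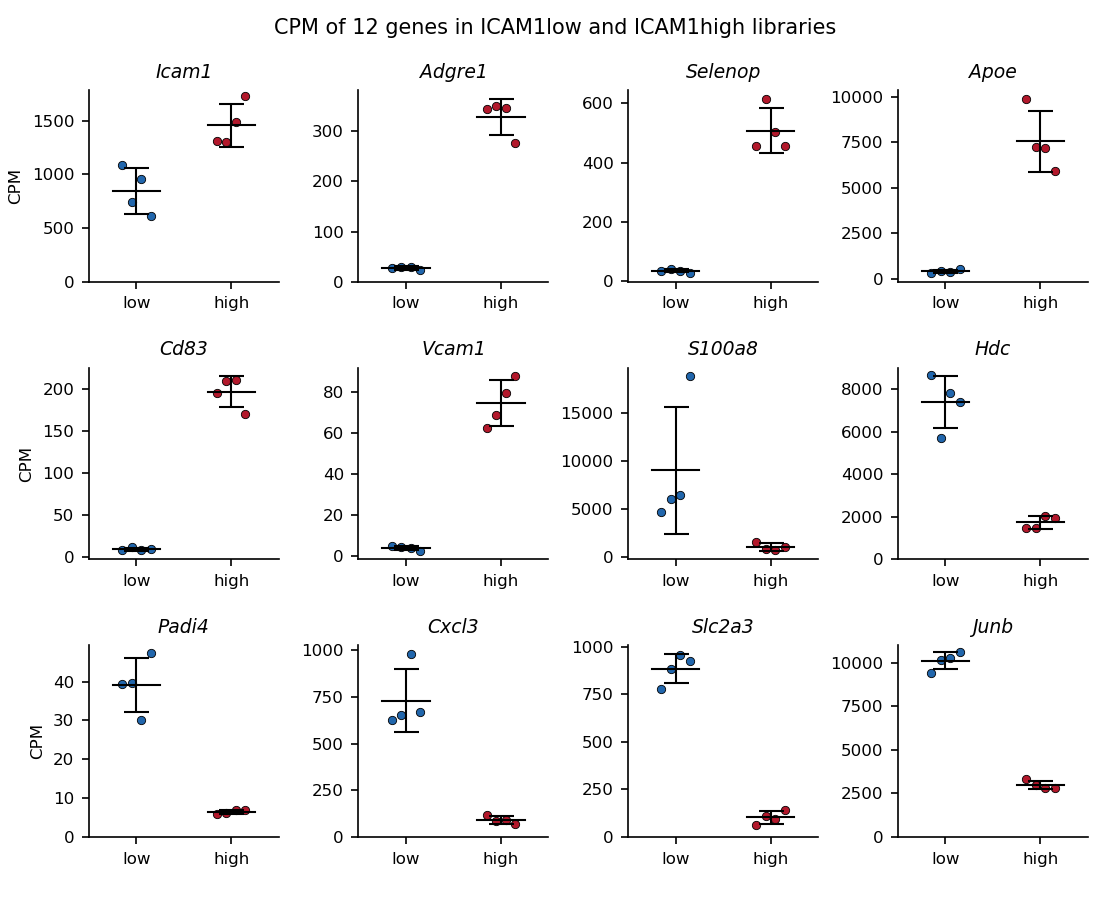
CPM of 12 genes is plotted per library for ICAM1low in blue and ICAM1high in red, with the mean and SD of 4 replicates as lines. The 4 libraries of a group lay on the same side of all 4 of the other for each gene, with Adgre1, Selenop, Apoe, Cd83, Vcam1 and Icam1 higher and S100a8, Hdc, Padi4, Cxcl3, Slc2a3 and Junb lower in ICAM1high.

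Adhesion and migration genes, the subject named in the title of the study, moved in both directions. Vcam1, an endothelial and macrophage ligand of alpha4 integrins, was at 74.7 ± 11.3 against 3.85 ± 0.940 CPM, and Sdc3, a cell-surface proteoglycan, at 304 ± 33.1 against 18.4 ± 3.91 CPM (SD, n = 4), with log2 fold changes of 4.28 (SE 0.23, adjusted p = 1.28e-06) and 4.05 (SE 0.20, adjusted p = 1.11e-06), whereas Cd44, a hyaluronan receptor picked after its value was seen, changed by -1.37 (SE 0.16, adjusted p = 0.000139). Of 44 adhesion genes besides Icam1, 11 rose, 15 fell and 18 did not pass, also when adjusted over the list alone, and under library totals 22 rose and 6 fell. The median was 0.06 and the mean 0.08, while camera ranked the list below other genes without passing (adjusted p = 0.790). Of 17 reverse migration and ageing markers, 11 fell and 2 rose (12 and 2 when adjusted over the list alone), with 7 that fell and 4 that rose under library totals, a median of -1.04 and an adjusted p of 0.00223 (adjusted p = 0.189 with an estimated correlation). Cxcr1, a receptor for CXC chemokines, changed by -2.88. Ctsc rose by 2.58 and Itgax, which encodes CD11c and was picked after its value was seen, by 1.5. Cxcr4, which retains neutrophils in the bone marrow and was picked after its value was seen, was at -0.55 (adjusted p = 0.0759) and at 0.12 under library totals. Of 31 receptors for chemoattractants and lipid mediators, 9 rose and 15 fell (9 and 16 when adjusted over the list alone), and 12 rose and 12 fell under library totals. C3ar1, the C3a receptor, rose by 4.46 and the leukotriene receptor Cysltr1 by 2.79. The median of these receptors was -0.73 and the mean 0.17, and camera placed them lower without passing (adjusted p = 0.271), although they passed as lower than other genes under library totals (0.0117). Among 44 chemokines and cytokines 15 rose and 12 fell (16 and 12 when adjusted over the list alone), and 24 rose and 10 fell under library totals, with an adjusted p of 0.848. The scavenger chemokine Cxcl16 rose by 3.89 and Cxcl14 by 4.08, whereas Cxcl3 changed by -2.99, from 731 ± 167 to 92.2 ± 21.8 CPM. Genes of macrophages rose in the same libraries, with a median of 3.82, and core neutrophil genes fell, with a median of -2.10.

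Genes of immune suppression, NF-kB, interferon and extracellular traps fell more often than they rose, but under library totals more rose than fell among NF-kB targets (11 and 7), interferon targets (13 and 6) and trap genes (7 and 4). Entpd1, an ectonucleotidase that lowers extracellular ATP, was at 251 ± 16.1 against 1196 ± 165 CPM and Acod1 at 2291 ± 428 against 9511 ± 1494 CPM (SD, n = 4), and Arg2, an arginase, changed by -1.81. In the immune suppression and PMN-MDSC list 15 of 31 genes fell and 4 rose (19 and 4 when adjusted over the list alone), and 11 fell and 9 rose under library totals, with a median of -0.996 and an adjusted p of 0.00121 (adjusted p = 0.189 with an estimated correlation). The members that rose, picked after their values were seen, were Arg1 at 2.46, Il10 at 2.34, Havcr2 at 1.15 and Dcstamp, which had 0 counts in ICAM1low. Of 40 NF-kB targets 20 fell and 5 rose, also when adjusted over the list alone, with a median of -0.54 that became 0.15 under library totals. Cd83 rose by 4.34, the inhibitor Tnip3 by 4.29 and Plau, the urokinase, by 2.33, and Cd40 at 3.82 and Bcl2a1d at 0.92, picked after their values were seen, also rose. Camera gave NF-kB targets an adjusted p = 0.00359, and an adjusted p = 0.464 with an estimated correlation. Type I and II interferon targets numbered 23 that fell and 8 that rose of 47 (24 and 8 when adjusted over the list alone), with a median of -0.59 that became 0.10 under library totals. Ifi44 rose by 3.07 and Ifi204 by 1.95, while the antiviral Oas3 changed by -1.51, and camera gave an adjusted p = 0.00223 (adjusted p = 0.461 with an estimated correlation). Among 22 genes of the NADPH oxidase and extracellular traps, 13 fell and 5 rose, also when adjusted over the list alone, with a median of -0.69 that became 0.00 under library totals. Padi4 and Gsdme, a pore-forming gasdermin, changed by -2.58 and -2.0, and Cybb rose by 2.40. Its other members that rose, picked after their values were seen, were Padi2 at 3.69, Hvcn1 at 2.76, Cat at 1.79 and Pycard at 1.76. Camera gave this list an adjusted p of 0.0541, which was 0.0236 without ICAM1high replicate 1, and 0.0261, 0.0449 and 0.0439 without ICAM1low replicate 1, 2 or 3. It was also 0.0165 with no filter, 0.0160 under library totals and 0.0478 without both ICAM1high replicate 1 and ICAM1low replicate 4. Matrix remodelling and angiogenesis genes were mixed, with 17 of 44 higher and 8 lower (19 and 10 when adjusted over the list alone), 23 and 5 under library totals, and an adjusted p of 0.353. Mmp12, the membrane metalloproteinase Mmp14 and the VEGF co-receptor Nrp1 rose by 5.17, 3.57 and 4.49. Macrophage markers rose in the same libraries, with a median of 3.82, core neutrophil genes fell, with a median of -2.10, and Arg2 overlaps Vti1b and Gsdme overlaps Mpp6 on the other strand.

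Glycolysis and hypoxia genes fell far more often than they rose in ICAM1high, although under library totals 8 hypoxia genes fell and 6 rose, and 11 glycolysis genes fell and 2 rose. Slc2a3, a high-affinity glucose transporter, was at 103 ± 33.6 against 884 ± 77 CPM and Slc16a3, the lactate exporter MCT4, at 588 ± 62.3 against 3336 ± 595 CPM (SD, n = 4), with log2 fold changes of -3.11 (SE 0.25, adjusted p = 1.17e-05) and -2.5 (SE 0.18, adjusted p = 6.39e-06), and Slc2a1, the glucose transporter GLUT1, changed by -1.74. Of 27 glycolysis genes 20 fell and 1 rose, also when adjusted over the list alone, with a median of -1.12 and an adjusted p of 2.38e-07 (adjusted p = 0.233 with an estimated correlation). The member that rose, picked after its value was seen, was the enolase Eno2 at 1.75. Of 34 hypoxia genes 19 fell and 3 rose (22 and 3 when adjusted over the list alone), with a median of -0.99, which was -0.30 under library totals, and an adjusted p of 6.92e-05 (adjusted p = 0.461 with an estimated correlation). Hif1a, the oxygen-regulated transcription factor, changed by -1.44 and Pfkfb4 by -1.33, and Selenbp1 at 2.60 and Rora at 1.30, picked after their values were seen, were 2 of the 3 that rose. Oxidative phosphorylation genes passed in few members, 8 higher and 1 lower of 55 (5 and 1 when adjusted over the list alone), with a median of 0.28, but 34 were higher and 0 lower under library totals, with a median of 0.98. Camera gave an adjusted p of 0.245, which was 0.0121 without ICAM1low replicate 4. Uqcrc2 of complex III rose by 1.01 and Atp5a1 of the ATP synthase by 0.86, and Ndufa5 of complex I changed by -1.13, lower in 3 of 4 same-numbered pairs, and did not pass under library totals (-0.45, adjusted p = 0.154). Stress response genes of the unfolded protein and integrated stress responses fell in 16 and rose in 11 of 37 members, also when adjusted over the list alone, with a median of -0.24 that became 0.47 under library totals and an adjusted p of 0.224. Sesn2, Xbp1 and Ddit3, which encodes CHOP, changed by -2.28, -1.61 and -1.54, and Ddit3 overlaps Mars on the other strand. In lipid handling and lysosome genes 17 of 44 rose and 10 fell (19 and 11 when adjusted over the list alone), and 25 rose and 4 fell under library totals, with a median of 0.54 and an adjusted p of 0.171. Apoe, a lipid carrier that is also a macrophage marker, was at 7555 ± 1673 against 408 ± 86.7 CPM, and Lpl, lipoprotein lipase, and Msr1, a scavenger receptor, rose by 4.28 and 3.76. Macrophage markers rose in the same libraries, with a median of 3.82, and core neutrophil genes fell, with a median of -2.10.

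All cell cycle genes that passed were higher in ICAM1high, and survival genes were mixed. E2f1, which drives entry into S phase, rose from 3.59 ± 0.250 to 13.8 ± 3.66 CPM, and the replicative helicase subunits Mcm3 and Mcm5 rose by 1.78 (SE 0.22, adjusted p = 0.000198) and 1.36 (SE 0.18, adjusted p = 0.000313) on the log2 scale. Of 40 cell cycle genes 19 rose and 0 fell (22 and 0 when adjusted over the list alone; 35 and 0 under library totals), with a median of 0.83, an adjusted p of 1.46e-05, and an adjusted p = 0.241 with an estimated correlation. Apoptosis and survival genes fell in 13 and rose in 6 of 35 members, also when adjusted over the list alone, with a median of -0.15 that became 0.53 under library totals. Mcl1, which keeps neutrophils alive, was at 3625 ± 34.3 against 8901 ± 536 CPM (SD, n = 4), and the kinase Pim1 and the TNF receptor Tnfrsf1a changed by -1.38 and -1.34. Camera gave apoptosis and survival an adjusted p of 0.0633, which was 0.0315 without ICAM1low replicate 2 and 0.0450 without ICAM1low replicate 3, and 0.0161 with no filter. Immediate early genes, which also respond to tissue dissociation, fell in 23 and rose in 4 of 31 members (23 and 5 when adjusted over the list alone), and under library totals 14 fell and 7 rose, with a median of -0.95 and an adjusted p of 9.41e-07 (adjusted p = 0.0900 with an estimated correlation). The AP-1 subunit Junb was at 2991 ± 239.8 against 10124 ± 488 CPM, and Btg2 and the phosphatase Dusp1 changed by -1.71 and -1.82. The 4 that rose, picked after their values were seen, were the heat shock genes Hspa1a at 0.79, Hspa1b at 0.57 and Hsph1 at 0.90, and Klf4 at 1.21. Macrophage markers had a median of 3.82 in the same comparison, and core neutrophil genes -2.10.

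Markers of other cell types also differed between the fractions. Keratins were lower in ICAM1high: Krt8, an epithelial keratin, was at 56.6 ± 7.93 against 157 ± 36.6 CPM, and Krt7 and the epithelial splicing factor Esrp1 changed by -1.30 and -1.24. Of 23 mammary tumour and epithelial markers 19 fell and 0 rose (20 and 0 when adjusted over the list alone), with a median of -1.41 and an adjusted p of 5.6e-09 (adjusted p = 0.189 with an estimated correlation). Under library totals 10 of these fell and Esrp1 was at -0.55 with an adjusted p of 0.0567. Only 7 of 25 T and NK cell markers were measured, of which 4 rose and 1 fell, also when adjusted over the list alone. Il7r, Cd4, Cd5 and Il2rb were higher by 4.83, 3.84, 1.47 and 3.27. Cd3d, part of the T cell receptor complex, changed by -1.27, which did not pass under library totals (-0.58, adjusted p = 0.0621). Camera gave this list an adjusted p = 0.0499 (adjusted p = 0.402 with an estimated correlation), which was 0.0841 without ICAM1high replicate 1 and 0.194 under library totals. Only 7 of 16 B and plasma cell markers were measured, of which 3 rose and 0 fell, also when adjusted over the list alone. Cd79b of the B cell receptor complex, the inhibitory co-receptor Cd22 and Ighm rose by 4.12 (5.15 without ICAM1low replicate 1), 2.92 and 2.91. The adjusted p was 0.0336 (adjusted p = 0.464 with an estimated correlation), and 0.106, 0.0703 and 0.0602 without ICAM1high replicate 1, ICAM1low replicate 2 or ICAM1low replicate 3. It was 0.169 under library totals and 0.0633 with no filter. Without both ICAM1high replicate 1 and ICAM1low replicate 4, T and NK cell markers had an adjusted p of 0.109 and B and plasma cell markers 0.0604. Dendritic cell markers split, 2 higher and 4 lower of 14, also when adjusted over the list alone, with a median of -0.05 but a mean of 0.53, and camera placed them higher without passing (adjusted p = 0.872). Irf8, a transcription factor of dendritic cells and monocytes, rose by 3.84 and Clec10a, picked after its value was seen, by 3.15, while Cd24a and Runx2 changed by -1.22 and -1.09, as did Fscn1 at -1.17 and Cacnb3 at -1.13, also picked after their values were seen. Under library totals, Runx2 was at -0.41 with an adjusted p of 0.107.

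Stromal markers passed in few members. Among 18 fibroblast and pericyte genes 3 rose and 2 fell (1 and 2 when adjusted over the list alone), with an adjusted p of 0.837: the contractile Acta2 and the matricellular Postn changed by -2.19 and -0.95, and Col1a2, Col3a1 and Thy1 rose by 1.24, 0.99 and 1.10. Among 17 endothelial genes 2 rose and 3 fell, also when adjusted over the list alone: Kdr, the VEGF receptor, and Eng rose by 2.05 and 1.68, and Plvap, Robo4 and Sox18 changed by -1.51, -1.97 and -1.90. The endothelial list had an adjusted p of 0.141, which was 0.00695 without ICAM1low replicate 3, 0.0161 with no filter and 0.0143 under library totals, and Postn (-0.26, adjusted p = 0.413) and Plvap (-0.85, adjusted p = 0.0597) did not pass under library totals. Plvap overlaps Gtpbp3 and Eng overlaps Fpgs on the other strand. Of 4 eosinophil, basophil and mast cell markers measured, Ear2 rose by 2.33, the eotaxin receptor Ccr3 changed by -1.60, and Kit, the stem cell factor receptor, changed by -0.99 (SE 0.36, adjusted p = 0.0458). Kit did not pass without any 1 of ICAM1high replicates 1, 2 and 3 (adjusted p = 0.0771, 0.115 and 0.0952) or ICAM1low replicates 1, 2, 3 and 4 (0.0704, 0.0850, 0.0565 and 0.0737). Among 3 red cell and platelet markers, the platelet integrin Itga2b changed by -1.03 and did not pass under library totals (-0.36, adjusted p = 0.289), Treml1 rose from near 0 counts, and Gp1ba was at 0.79 (SE 0.56, adjusted p = 0.281). Col3a1, Thy1, Robo4, Sox18, Ear2 and Treml1, like Cd5 and Il2rb among the lymphocyte markers, were picked after their values were seen. Mean log2 CPM of the macrophage list differed by 3.4 between the fractions, that of the epithelial list by -1.33, and that of the dendritic list by 0.70 (exact permutation p = 0.0286 for each, n = 4). The fibroblast and endothelial lists differed by -0.01 and -0.48 (exact permutation p = 0.971 and 0.314). The eosinophil, basophil and mast cell list differed by -0.004, and the 3 red cell and platelet genes by 1.06 (exact permutation p = 0.0286 for the latter).

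Immunoglobulin genes took a larger share of counts in ICAM1high. Mitochondrial genes took 0.692 ± 0.122% of counts in ICAM1high and 0.487 ± 0.146% in ICAM1low (SD, n = 4, exact permutation p = 0.114). Ribosomal protein genes took 1.76 ± 0.499% and 0.994 ± 0.311% (exact permutation p = 0.0571, n = 4). Haemoglobin genes took 7.09e-05 ± 2.32e-05% and 0.000159 ± 0.000156% (exact permutation p = 0.429, n = 4), with the ICAM1low mean raised by replicate 3 at 0.000371%. Immunoglobulin genes took 0.00822 ± 0.00378% and 0.000769 ± 0.000505% (exact permutation p = 0.0286, n = 4). After adjustment over the 16 measures the immunoglobulin difference had p = 0.0457 (exact permutation, n = 4), and it was higher in ICAM1high in 4 of 4 same-numbered pairs.

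**Figure D4:**
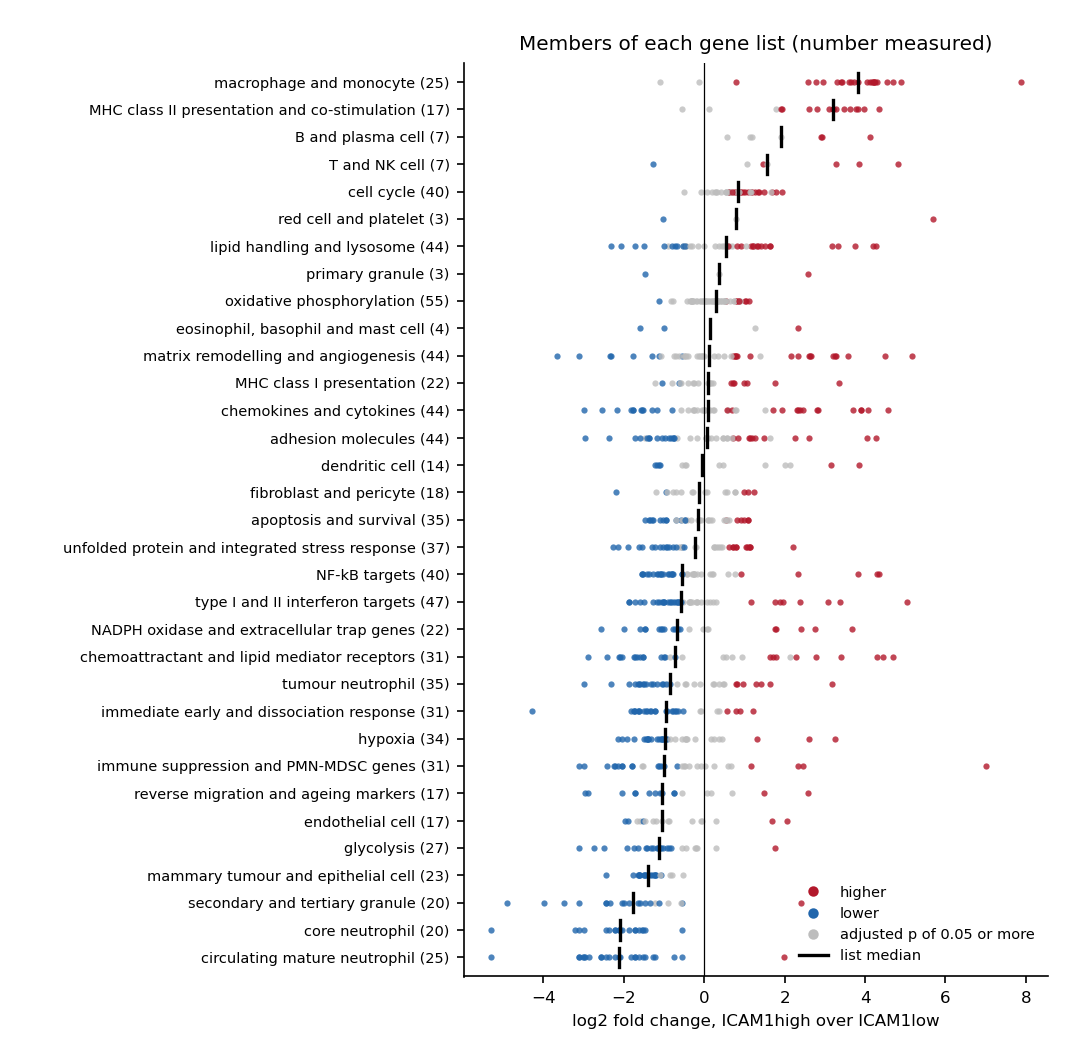
Each point is a measured member of a gene list, placed by its log2 fold change of ICAM1high over ICAM1low and coloured by direction where its adjusted p was under 0.05, with a bar at the list median. Medians ran from -2.11 for circulating mature neutrophils to 3.82 for macrophages, and those of NF-kB targets, interferon targets, the stress responses, apoptosis, dendritic and fibroblast genes turned positive under library totals, where that of NADPH oxidase and trap genes was 0.00.

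The library numbers fell into 2 runs, one holding replicates 1 and 2 and another holding replicates 3 and 4, so each gene was tested for a fraction difference that depended on the run. edgeR found 0 such genes among 14051, with 1606 at an unadjusted p under 0.05 and a smallest adjusted p of 0.417. DESeq2 also found 0, with 2055 of 25567 at an unadjusted p under 0.05, as did edgeR with a replicate block, with 664. The 1606 and 2055 exceed a share of 0.05 of the genes, which no dependence would give on average, and the 664 do not. In simulated data edgeR found only 25.8% of 4-fold interactions, so a dependence on the run is not excluded. The fraction difference within replicates 1 and 2 gave 1708 higher and 1416 lower genes, and within replicates 3 and 4 it gave 1658 and 1604. Genes such as Padi4, Adgre1 and Hdc kept their direction and passed in both runs.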

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

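The transcript length test and the alternative that leaves out ICAM1high replicate 1 and ICAM1low replicate 4 together were chosen only after the result was seen. Among 258 groups of 4 values, 12 had a highest or lowest library that stood apart from the other 3 by most of the range of the group, about as many as the 1 in 20 that chance gives. Each gap is the distance of that library to the nearest other, as a share of that range.

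Several of these lay in ICAM1high replicate 1. Its mitochondrial share was the highest of its group at 0.874% against 0.612 to 0.652% (gap 0.846). The mean log2 CPM of dendritic cell markers was also highest there, at 3.48 against 3.02 to 3.10 (gap 0.830). Cd79b, of the B cell receptor complex, was highest there at a log2 CPM of 3.34 against 1.79 to 1.98 (gap 0.880). Gp1ba, of the platelet receptor for von Willebrand factor, was lowest there at 0.24 against 1.72 to 1.84 (gap 0.926).

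ICAM1high replicate 4, the smallest library, had the highest Rdh12, at 5.73 against 5.34 to 5.36 (gap 0.950). It had the lowest Adgre1, which encodes F4/80, at 8.11 against 8.43 to 8.45 (gap 0.941). Krt7 was also lowest there, at 3.03 against 3.59 to 3.65 (gap 0.905). In ICAM1high replicate 2, Entpd1 was lowest at 7.82 against 8.01 to 8.03 (gap 0.889). In ICAM1high replicate 3, the haemoglobin share was highest at 0.000105% against 5.7e-05 to 6.3e-05% (gap 0.875). Among ICAM1low libraries, Zmynd15 was highest in replicate 1, at 3.21 against 2.49 to 2.58 (gap 0.881). Cxcl3 was highest in ICAM1low replicate 3, at 9.94 against 9.29 to 9.38 (gap 0.855). E2f1 was lowest in ICAM1low replicate 3, at 1.74 against 1.92 to 1.95 (gap 0.892).

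ICAM1high replicate 1 and ICAM1low replicate 4 stood apart from their groups in the balance of short and long genes: the short minus long gap was -1.95 against -2.82 to -2.71 and -1.61 against -2.53 to -2.19. The tables argue against GC content as the shared cause, since the GC gap of ICAM1low replicate 4 lay inside the other 3 (-0.40 ranges beyond them), but that of ICAM1high replicate 1 lay 0.942 ranges beyond its group, so GC stays open for that library. They argue against library size too, since after thinning to equal depth the libraries still lay 3.66 and 1.62 ranges beyond the others of their groups. A shift by transcript length, as RNA integrity or fragment size may give, stays open as a candidate explanation, with distances of 6.89 and 1.71 ranges. A biological difference between these tumours was not tested.

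Across 14051 genes, which are not independent replicates, the log2 fold change between the fractions followed gene length with a Spearman rho of 0.10, and without both libraries 7027 genes passed, 118.7% of the 5920 with all libraries. Apart from those libraries, the short minus long gap was lower in ICAM1high (-2.82 to -2.71) than in ICAM1low (-2.53 to -2.19). The gap thus also differed between the fractions, and whether transcript length adds to their differences is not settled.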

How the results depend on the processing

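Scaling by library totals, the same with fry, leaving out ICAM1high replicate 1 and ICAM1low replicate 4 together, and equal depth were chosen after the data were seen. Simulated 1.5-fold changes were almost never found (1.49%), but thinning to equal depth barely moved the counts of genes, while replicates differed by at least 12.8 times the variance of counting. Of 2373 values of 108 named genes under the alternatives, 2339 kept direction and side of the threshold, 32 kept direction but no longer passed, 1 newly passed (Cd63 under library totals) and 1 turned (Cd63 in replicates 3 and 4 alone, -0.37, adjusted p = 0.291). The 4 counts of genes stayed within 1.5 times their values under DESeq2 (3368 higher, 3239 lower), limma-voom (3383, 2743), RLE (2948, 3014), upper-quartile scaling (3063, 2851), no filter (3162, 2558), the strict filter (2759, 2511), robust dispersion (3154, 2733), the run as a covariate (2927, 2475), equal depth (3057, 2721) and without both libraries (3586, 3441). The replicate block gave 2263 and 1975, with 1798 and 1393 changed at least 2-fold. Calls shared with it made up 71.1% of the 5920, against 98% for DESeq2, 95.6% without both libraries and 67.8% under library totals, and every shared call kept its direction. Under library totals, 389 of the 5920 changed sign without passing. Differences in shares of counts moved by less than 1 SD without any single library. Leaving out 1 of 4 values cannot move a mean by more than that, so this does not show that the shares are stable. A sign-flip test over the 4 same-numbered pairs cannot go below an exact p of 0.125.

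Fewer samples gave 1708 higher and 1416 lower genes in replicates 1 and 2, and 1658 and 1604 in replicates 3 and 4. Library totals gave 6818 higher and 839 lower, and 5136 and 397 at least 2-fold, since that scaling moves the median fold change up by 0.68. Leaving out each library gave 2345 to 3403 higher, 2157 to 2927 lower, 1761 to 2213 at least 2-fold higher and 1480 to 1843 at least 2-fold lower genes, with 3 to 6 lists higher and 12 to 15 lower.

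Lists called higher or lower numbered 0 and 0 with an estimated correlation, alone or with the block. Lists higher numbered 8 with fry, 3 with the strict filter (T and NK and B and plasma cell lists then had too few members), 3 under library totals and 3 without both libraries. Library totals with fry gave 18 higher and 6 lower. The cause was not tested for the other moves.

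Direction turned in these lists, with the adjusted p of each. Chemokines and cytokines turned with no filter (0.893), the strict filter (0.927), library totals (0.635) and without ICAM1high replicate 1 (0.946) or ICAM1low replicate 2 (0.862), within 0.548 to 0.956 over single libraries left out. Dendritic markers turned with the strict filter (0.815), library totals (0.650), without both libraries (0.894) and without ICAM1high replicate 1 (0.997), within 0.473 to 0.997. Endothelial markers turned with the strict filter (0.964). Class I presentation turned without both libraries (0.894), ICAM1high replicate 1 (0.632) or ICAM1low replicate 2 (0.774), within 0.520 to 0.956. Fibroblast markers turned without ICAM1low replicate 2 (0.884) or ICAM1high replicate 3 (0.827), within 0.632 to 0.979. With fry, adhesion (0.0753), chemoattractant receptors (0.339) and fibroblast markers (0.955) turned. With fry under library totals, these 3 (0.000862, 0.00139 and 0.0476), endothelial markers (0.613), tumour neutrophil genes (0.321), NF-kB targets (0.00289), interferon targets (0.0119), NADPH oxidase (0.0599), stress response (0.0017) and apoptosis genes (3.7e-05) turned upward; fry does not compare with other genes, so the upward shift of that scaling enters it. With fry under TMM, NF-kB targets no longer passed (0.0951), while matrix (0.00179), lipid (0.000756), stress response (0.0198), apoptosis (0.00318) and dendritic genes (0.0384) did. With fry under library totals, reverse migration (0.122), immune suppression (0.805) and hypoxia genes (0.805) no longer passed.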

Other observations

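The tests of macrophages, of dilution, of a neutrophil state and of library scaling were chosen only after the result was seen; the counts over other splits were planned. Several inflammatory mediators and integrin chains, picked after their values were seen, were also compared. Il1b, the cytokine interleukin 1 beta, was at 7387 ± 1575 against 21708 ± 2506 CPM (SD, n = 4), with a log2 fold change of -1.56 (SE 0.19, adjusted p = 0.000143). Ptgs2, the inducible cyclooxygenase, was at 2824 ± 828 against 5904 ± 1865 CPM with -1.06 (SE 0.29, adjusted p = 0.0143), and at -0.38 (adjusted p = 0.318) under library totals. Tnf was at 0.76 (SE 0.32, adjusted p = 0.0811), Ccl3 at -0.25 (SE 0.38, adjusted p = 0.626) and Ccl4 at 0.21 (SE 0.40, adjusted p = 0.703), none of which passed. Siglecf, a sialic acid-binding lectin of eosinophils and of a subset of tumour neutrophils, rose from 70.7 ± 11.4 to 138 ± 21.9 CPM, with a log2 fold change of 0.96 (SE 0.17, adjusted p = 0.00160). The checkpoint ligand Cd274 was at -0.48 (SE 0.18, adjusted p = 0.0531), and at 0.21 under library totals. The chains of the integrins that bind ICAM1 changed by -0.82 (SE 0.13, adjusted p = 0.000758) for Itgb2, -1.04 (SE 0.20, adjusted p = 0.00212) for Itgal and -0.75 (SE 0.19, adjusted p = 0.00996) for Itgam, all lower in ICAM1high, and none of the 3 passed under library totals (-0.13, -0.36 and -0.06).

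Macrophage and monocyte genes were higher in ICAM1high, among them Apoe at 7555 ± 1673 against 408 ± 86.7 CPM, C1qa at 1184 ± 478 against 60.3 ± 16.6 CPM and Selenop at 507 ± 75.3 against 35.9 ± 5.29 CPM. Library scaling is argued against, since it moves all genes of a library alike and the median of the list lay 3.74 above that of all tested genes. Macrophages among the ICAM1high cells remain a candidate explanation: 23 of 25 markers passed as higher, abundant ones included, and none of the 25 is a core neutrophil gene (2 are also in the receptor list, 1 in the matrix list and 1 in the lipid list), although ICAM1low also holds transcripts of the list (mean log2 CPM 3.31). The markers used to gate neutrophils, which could remove macrophages, are not given in the sources used here. Expression of these genes by ICAM1high neutrophils themselves cannot be told apart from this, because the fall of all 20 core neutrophil genes is allowed by both and each library sums over cells.

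Core neutrophil genes were lower in ICAM1high, and library scaling as the whole cause is argued against, since their median was -1.40 under library totals. Dilution of otherwise equal neutrophils by other cells may contribute, and it needs the genes to fall by 1 factor. Of the 20 genes, 7 lay more than 2 standard errors from the list median. This is between bounds of 3 and 8 that were set after the result was seen. Among the 7, Mmp9 at -0.56 and Csf3r at -1.47 fell least, 9.43 and 4.32 standard errors above the median. Retnlg at -5.31 (-4.19 without ICAM1low replicate 4) fell most, at -4.13 standard errors from it. Dilution by 1 factor alone does not give these distances, although most of the list lay within 2 standard errors. A different state of the ICAM1high neutrophils cannot be told apart from dilution. The granule list median of -1.76 differed from Csf3r by -0.29 but lay above the core list median of -2.10, so its direction depends on the reference. Other cells that carry Csf3r would also give the same ratio to Csf3r. Markers of other cells moved apart: the mean log2 CPM differed by -1.33 for epithelial and 3.4 for macrophage markers. It differed by 1.97 for T and NK and 2.03 for B and plasma markers, of which only 7 of 25 and 7 of 16 were measured. Dendritic markers differed by 0.70, but 2 of 14 rose and 4 fell, with a median of -0.05, so they show no clear gain. The spread between cell types runs against an even gain of all other cells. A gain of macrophages, or of lymphocytes on these few markers, stays open.

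Other splits of the 8 libraries into 4 and 4 gave 0 genes in either direction as the highest. The real split gave 3172 higher and 2748 lower genes, 2115 and 1704 of them at least 2-fold. It ranked first for each count (1 of 35 splits), which is the smallest share that 35 splits allow. The 0 is no measure of size, because each other split mixes the fractions and their difference enters its spread. For lists, chance is not excluded, and these splits cannot judge it. At least 5 lists in a direction came from 25 of 35 splits and at least 12 from 10 of 35. The highest of the others gave 16. Splits that hold 3 libraries of 1 fraction together keep part of the real difference, so they give no level for chance. Of the others with at least 5 lists, 16 held 3 libraries of 1 fraction together and 8 held 2 of each, and of those with at least 12, 8 and 1 did.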
